A study of Mus musculus with 6 samples.

How the data were processed

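The data are RNA-seq profiles of GFP-positive cells sorted from mouse kidneys at embryonic day 15.5, 3 control and 3 Ash2l cKO libraries. Per the labels' protocols, kidneys were trypsinized, GFP-positive cells were sorted, RNA was isolated with a micro-scale column kit and a service company made and sequenced the libraries. The submitters' processing notes name HISAT2 2.2.1.0, HTSeq 0.9.1, DESeq2 1.20.0, DESeq 1.18.0 and the genome build GRCm39, without the settings. Whether the counting used strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart.

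The authors deposited FPKM values per gene and library, which divide reads by gene length and library total, for 17605 genes, with gene symbols and Entrez identifiers. A second deposited table holds the authors' comparison of cKO with control, with a ratio of the groups as a fold change, a p-value and a q-value per gene. In the authors' table, a gene is marked as up or down at a q-value below 0.05 and a fold of at least 2 or at most 0.5.

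The files hold FPKM and no read counts. Each gene's FPKM values are whole multiples of what 1 read is worth, so reads were recovered from them. All 17605 genes (100.0%) came out as whole numbers within a relative tolerance of 1e-12. The totals behind the FPKM values were 33222268 to 34960432 reads per library, and the listed genes held 99.77% to 99.78% of them. Their absolute scale was set by taking the smallest whole totals that give the ratios between libraries. As a check of that scale, the recovered length of 570 genes equals the gene span in RefSeq's GRCm38.p6 table. That assembly differs from the authors' build, so no coordinates are printed, and the table was used otherwise for gene types alone, with 17497 genes matched by Entrez identifier.

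Because the deposited unit is FPKM, the main test was limma on log2(FPKM + 1), with an empirical Bayes trend, over the 10749 genes with at least 1 FPKM in at least 3 libraries. The pseudocount of 1 understates the fold changes of genes with low values. All 6 libraries entered 1 fit with genotype as its term. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are cKO over control, with the standard error of the fit, and FPKM values are means ± SD over 3 libraries. No pair of libraries agreed within sampling noise.

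The comparison, the tests, 28 gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. Of the lists, 26 were written gene by gene and 2, ribosomal proteins and replication-dependent histones, were defined by symbol. Lists were tested with limma's camera at a preset correlation between genes of 0.01, as a family of 28 under Benjamini-Hochberg, with an estimated correlation and with fry beside it. With an estimated correlation no list passed the threshold. The named genes are Ash2l, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and whose higher mean is at least 2 FPKM, up to 4 members of each list with the smallest p-values (8 for the progenitor, replication, mitotic and p53 lists), and Six2, Cited1, Cdkn1a, Cdkn1c, Mki67 and Wnt4. Further members are named where the count of genes that passed or did not pass was small, or as examples, after their values were seen. Some genes that this rule names are not reported here. Chromaffin, Y-linked, MHC class II and muscle genes were also chosen after the data were seen.

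The same steps were checked on simulated data with the real genes' means. Of 67 genes changed 1.5-fold 47.8% were recovered, of 67 changed 2-fold 98.5% and of 66 changed 4-fold 100%, with 8 false calls among 172. The simulation gave every gene the same dispersion, 0.02, changed few genes and drew them from those with higher values. Real genes differ in their spread, so these shares need not hold for them. Alternatives varied the scaling, pseudocount, filter, test, threshold, replicate block and libraries. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.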

Results

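RNA was sequenced from green fluorescent cells sorted out of mouse embryonic kidneys at stage E15.5. In these embryos a Cre recombinase fused to GFP is driven by Six2, a transcription factor of nephron progenitors, so that the sort collects progenitors and cells derived from them. The control group held 3 libraries from embryos with 1 floxed copy of Ash2l. The conditional knockout (cKO) group held 3 libraries from embryos with both copies floxed. Ash2l encodes a core subunit of the complexes that methylate lysine 4 of histone H3. The title of the series asks how ASH2L regulates cell cycle genes, progenitor self-renewal and nephron formation. The labels call the libraries of a group biological replicates and do not say how many embryos went into each. The totals behind the FPKM values ranged from 33222268 to 34960432 reads per library, a ratio of 1.05.

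Ash2l itself (Entrez 23808) stood at 48.6, 52.4 and 54.9 FPKM in the 3 control libraries and at 16.9, 25.4 and 22.2 FPKM in the 3 cKO libraries. The group means were 52.0 ± 3.18 and 21.5 ± 4.30 FPKM (SD, n = 3 each), a log2 fold change of -1.25 ± 0.15 (SE, limma, Benjamini-Hochberg adjusted p = 0.000781). A value for the whole gene also counts reads outside the deleted exons, and the controls carry a floxed copy as well. Across the transcriptome, 1479 genes were higher and 1257 lower in the cKO libraries, 2736 of the 10749 tested (limma, adjusted p below 0.05). At least a 2-fold change was found for 404 of the higher and 380 of the lower genes. The 3 values of the groups did not overlap for 4519 genes, or 42% of those tested, where chance gives 10%. Correlations of log2 values across genes, which are not independent replicates, were 0.981 to 0.987 within the control group, 0.976 to 0.986 within the cKO group and 0.944 to 0.957 between groups. Upper-quartile scaling, chosen after the data were seen, gave 1176 higher and 1492 lower genes. The count fell to 1818 without control 2, to 805 and 784 lower genes without control 2 and control 3, and to 923 higher genes without cKO 1.

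**Figure D1:**
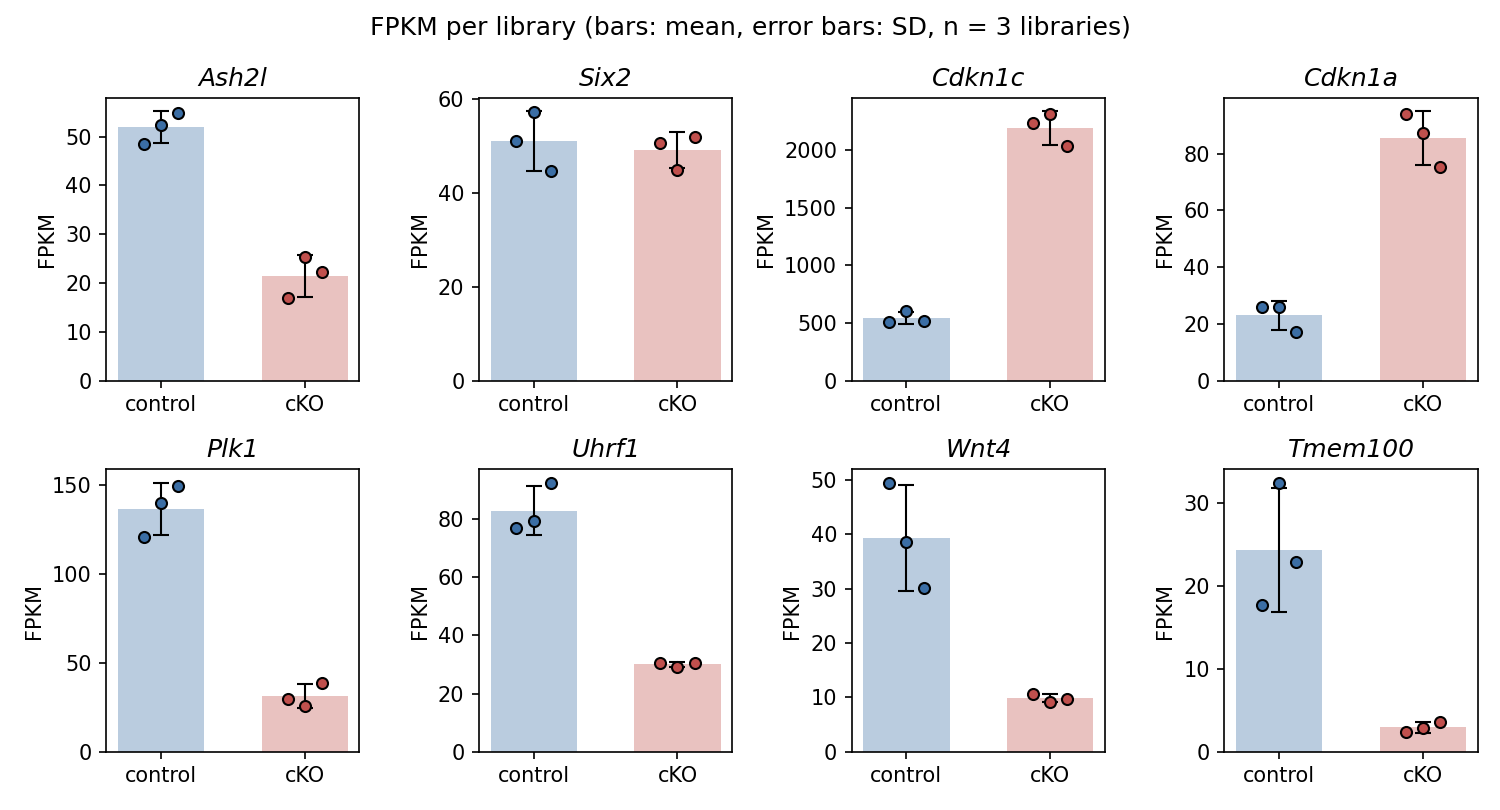
FPKM (vertical axes, from 0) of 8 genes in control (blue) and cKO (red) libraries, where points are libraries, bars are means and error bars are the SD of n = 3. Ash2l, Plk1, Uhrf1, Wnt4 and Tmem100 lay lower and Cdkn1c and Cdkn1a higher in every cKO library than in every control library, while the values of Six2 overlapped.

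Genes of the dividing cell were lower throughout the cKO libraries. Of 71 genes of G2 phase and mitosis, 64 fell and none rose, and of 63 genes of DNA replication and S phase, 49 fell and none rose. Plk1, a kinase of mitotic entry, fell from 137 ± 14.6 to 31.4 ± 6.77 FPKM (SD, n = 3 each), and Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell with a log2 fold change of -1.32 ± 0.09 (SE, limma, adjusted p = 0.000101). Uhrf1, which keeps DNA methylation through replication, fell from 82.8 ± 8.38 to 30.0 ± 0.795 FPKM, and Mcm10, a replication initiation factor, from 11.5 ± 1.2 to 3.15 ± 0.146 FPKM. The proliferation marker Mki67 fell from 4.25 ± 0.387 to 1.71 ± 0.156 FPKM.

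The median log2 fold change was -0.95 over the mitotic list and -0.66 over the replication list (camera, adjusted p = 7.22e-31 and 3.96e-22). With an estimated correlation between genes, the adjusted p was 0.144 and 0.0942. Adjusted over the list alone, 67 mitotic and 55 replication genes fell. Cdk1 had a log2 fold change of -1.33 ± 0.10, Ccna2 of -1.27 ± 0.10, Birc5 of -1.12 ± 0.09, Smc4 of -1.37 ± 0.12, Mybl2 of -1.88 ± 0.17 and Cenpa of -1.05 ± 0.10 (SE, limma, adjusted p from 0.000127 to 0.000262). Among replication genes, Rrm1 had a log2 fold change of -1.15 ± 0.10, Rrm2 of -1.05 ± 0.09, Tyms of -0.98 ± 0.10, Mcm3 of -0.79 ± 0.09, Mcm7 of -0.80 ± 0.09 and Tk1 of -1.34 ± 0.16 (SE, limma, adjusted p from 0.000182 to 0.00072). The 7 mitotic genes that did not pass were Bora, Cdc25b, Cenpm, Ckap5, Kif18a, Ncapd2 and Pttg1. Replication-dependent histone genes, which are transcribed in S phase, followed with 30 of 54 lower and none higher, 37 when adjusted over the list alone. H3c3 fell from 13.6 ± 2.85 to 3.20 ± 0.856 FPKM, H2bc14 from 15.3 ± 1.03 to 3.05 ± 1.48, H2ac20 from 5.05 ± 1.29 to 0.965 ± 0.229 and H1f5 from 17.3 ± 4.94 to 4.68 ± 1.43. As a list, histone genes had a median log2 fold change of -0.88 (camera, adjusted p = 5.85e-12, and adjusted p = 0.141 with an estimated correlation). Histone genes are near-identical copies of each other, so values of single members are uncertain. In the deposited annotation's pathways, examined after the data were seen, 45 of 111 cell cycle genes were lower and 6 higher, and 21 of 35 DNA replication genes lower and 1 higher (camera, adjusted p = 6.21e-06 and 1.43e-06, and adjusted p = 0.66 for both with an estimated correlation).

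The cyclin-dependent kinase inhibitor genes Cdkn1c and Cdkn1a rose. Cdkn1c (p57) rose from 544 ± 55.0 to 2192 ± 144 FPKM, a 4.03-fold difference of means, and Cdkn1a (p21) rose 3.71-fold from 23.0 ± 5.08 to 85.5 ± 9.36 FPKM (SD, n = 3 each; limma, adjusted p = 2.76e-05 and 0.000215). They were the 2 members that rose among 18 tested genes of G1 control, of which 6 fell. The inhibitor genes Cdkn1b, Cdkn2c and Cdkn2d did not pass, with log2 fold changes of -0.57, 0.42 and 0.20 (limma, adjusted p = 0.118, 0.230 and 0.191). Cyclin D1 (Ccnd1) fell from 50.7 ± 5.04 to 19.9 ± 3.08 FPKM and Rbl1, a pocket protein, from 12.6 ± 0.168 to 6.98 ± 0.273 FPKM (limma, adjusted p = 0.000467 and 0.00427). Ccnd2, Cdk4, Cdk2 and E2f4 were the others that fell. The list as a whole did not pass the test, with a median log2 fold change of -0.09, a mean of 0.07 and a camera direction of down (adjusted p = 0.599). Adjusted over the list alone, 4 members rose and 6 fell.

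Of 26 tested genes on a list of targets that the tumour suppressor p53 activates, 14 rose and 1 fell, against 17 and 2 when adjusted over the list alone. Ccng1 rose from 7.95 ± 0.539 to 28 ± 0.577 FPKM, Ddit4l from 5.45 ± 1.71 to 19.5 ± 5.74, Trp53inp1 from 1.98 ± 0.337 to 6.57 ± 1.01, Eda2r from 0.873 ± 0.443 to 3.92 ± 0.481 and Dcxr from 10.4 ± 2.48 to 26.8 ± 2.66 FPKM (SD, n = 3 each). Bbc3, which encodes the cell death activator PUMA, rose from 14.3 ± 0.737 to 26.0 ± 0.551 FPKM. Psrc1, a spindle gene that also stands on the mitotic list, was the member that fell, from 44.2 ± 4.16 to 23.5 ± 3.16 FPKM. The adjusted p of these 7 genes ranged from 0.000101 to 0.00241 (limma). Cdkn1a belongs to this list as well as to that of G1 control. The p53 list had a median log2 fold change of 0.51 (camera, adjusted p = 6.35e-05, and adjusted p = 0.116 with an estimated correlation). The wider p53 signalling pathway of the deposited annotation, examined after the data were seen, did not pass, with 14 of 60 genes higher and 16 lower (median -0.0135, camera direction down, adjusted p = 0.823).

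Of 19 tested genes of the apoptosis machinery, 5 rose and 3 fell. Pmaip1 (NOXA) rose from 0.861 ± 0.353 to 5.21 ± 2.29 FPKM and Bax from 209 ± 25.3 to 309 ± 38.4 FPKM (SD, n = 3 each; limma, adjusted p = 0.00368 and 0.00952). Casp8 fell from 8.45 ± 0.923 to 4.60 ± 0.904 FPKM (limma, adjusted p = 0.0155), a call lost without control 2 (adjusted p = 0.0594) or without control 3 (0.0574). The list did not pass (median log2 fold change 0.15, camera, adjusted p = 0.324, and 0.00317 upward with fry, which does not compare it with other genes), and adjusted over the list alone 5 members rose and 4 fell.

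Markers of the nephron progenitor changed in both directions, more of them down. Six2, whose regulatory sequence drives the Cre, stood at 51.0 ± 6.29 FPKM in control and 49.1 ± 3.79 FPKM in cKO libraries (SD, n = 3 each), a log2 fold change of -0.05 ± 0.12 (SE, limma, adjusted p = 0.793). Of 23 tested markers 14 fell, among them Tmem100 from 24.3 ± 7.50 to 2.95 ± 0.664 FPKM, Sall1 from 23.6 ± 1.94 to 10.8 ± 0.974, Wt1 from 65.3 ± 8.97 to 31.4 ± 4.84, Uncx from 94.5 ± 13.5 to 43.5 ± 8.40, Itga8 from 15.4 ± 2.15 to 6.73 ± 0.679 and Hoxa11 from 85.5 ± 7.64 to 43.2 ± 9.20 FPKM. The 3 that rose were the transcription factor gene Meox1, from 20.8 ± 2.17 to 57.3 ± 6.50 FPKM, and the growth factor genes Fgf9, from 2.88 ± 0.246 to 11.8 ± 2.22 FPKM, and Fgf20, from 25.8 ± 10.7 to 76.6 ± 27.3 FPKM (limma, adjusted p = 0.00904). The adjusted p ranged from 0.000192 to 0.00221 for Tmem100, Sall1, Wt1, Uncx, Itga8, Hoxa11, Meox1 and Fgf9 (limma).

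The median log2 fold change of the progenitor list was -0.69 (camera, adjusted p = 0.000585, and adjusted p = 0.261 with an estimated correlation), and the counts adjusted over the list alone were the same 3 and 14. Cited1, which marks the least committed progenitors, stood at 164 ± 17.8 FPKM in control and 123 ± 10.7 FPKM in cKO libraries (SD, n = 3 each; limma, adjusted p = 0.0204). That call was lost without control 2 (adjusted p = 0.0824), without cKO 1 (0.0702) and without cKO 2 (0.0640). The 6 tested markers that did not pass were Six2, Meox2, Crym, Rspo1, Robo2 and Dpf3.

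Genes of the first steps of nephron formation and of the maturing tubule were lower in cKO libraries. Wnt4, the signal that starts the conversion of progenitors to epithelium, fell from 39.4 ± 9.73 to 9.86 ± 0.757 FPKM, and Osr2 fell from 24.6 ± 5.76 to 7.56 ± 2.57 FPKM (SD, n = 3 each; limma, adjusted p = 0.00028 and 0.00203). Of 21 tested genes of the pretubular aggregate, renal vesicle and S-shaped body 12 fell, including Fgf8, Lhx1 and Pax8, and 1 rose. The gene that rose was Cxcl12, a chemokine, from 7.41 ± 0.663 to 20.9 ± 0.616 FPKM (limma, adjusted p = 0.000292). Among proximal tubule markers 9 of 11 fell and none rose. The phosphate transporter gene Slc34a1 fell from 7.54 ± 4.52 to 0.0999 ± 0.173, the sodium pump regulator gene Fxyd2 from 19.6 ± 13.1 to 1.82 ± 0.358 and Slc27a2 from 1.78 ± 0.270 to 0.0647 ± 0.112 FPKM (limma, adjusted p from 0.000786 to 0.0015).

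The median log2 fold change was -0.75 for the early nephron list (camera, adjusted p = 0.000431, and adjusted p = 0.261 with an estimated correlation) and -2.16 for the proximal tubule list (camera, adjusted p = 8.48e-07, and adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone, the counts were the same as over all genes for both lists. Of 9 tested podocyte markers, 2 fell and 1 rose, against 5 and 1 when adjusted over the list alone, with a median log2 fold change of -0.53 (camera, adjusted p = 0.0259, and adjusted p = 0.386 with an estimated correlation). Foxc2 fell from 23.0 ± 5.32 to 7.54 ± 1.71 FPKM and Dpp4 from 2.12 ± 0.00777 to 0.0880 ± 0.0443 FPKM (limma, adjusted p = 0.00145 and 0.000536). Of 6 tested loop and distal tubule markers 2 fell, also over the list alone. They were Ppp1r1a, from 43.5 ± 4.34 to 7.04 ± 4.06 FPKM, and Tmem52b, from 3.58 ± 3.48 to 0.202 ± 0.209 FPKM (limma, adjusted p = 0.000953 and 0.0218). Tmem52b lost its call without cKO 1 (adjusted p = 0.0734) or cKO 2 (0.0567). The loop and distal list did not pass (median log2 fold change -0.89, camera, adjusted p = 0.133, and 0.0253 with fry), and its median was -0.57 without control 1, -0.51 without control 2, -0.52 without cKO 3 and -1.23 without cKO 2. Without control 1 the adjusted p was 0.162 for the podocyte list and 0.0566 for the proximal tubule list, and the podocyte list also missed the threshold without control 3 (0.116). The proximal tubule median moved to -1.47 without control 1, -1.43 without control 2 and -1.56 without control 3.

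**Figure D2:**
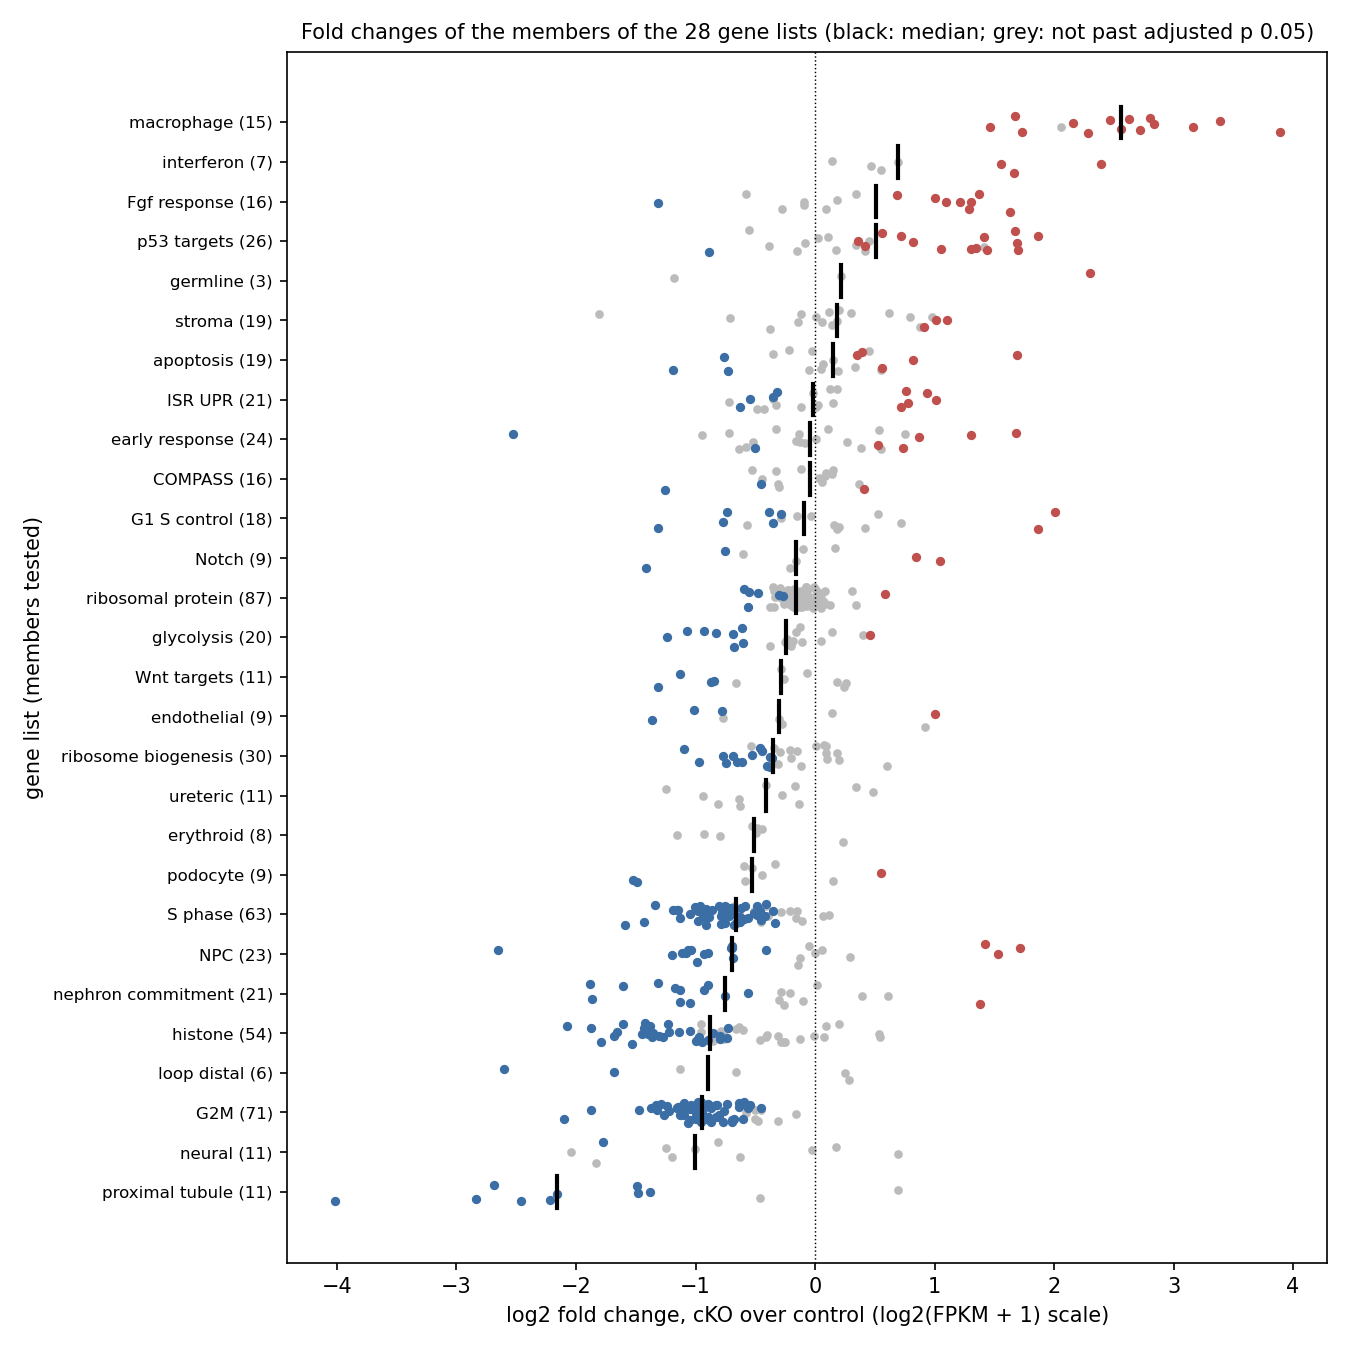
Log2 fold change, cKO over control, on the log2(FPKM + 1) scale (horizontal axis) of each tested member of 28 gene lists (vertical axis, with the number tested), where red and blue points passed the adjusted p of 0.05, grey points did not and black bars are medians. The median was 2.56 for the macrophage list, 0.51 for the p53 target list, -0.95 for the mitotic list and -2.16 for the proximal tubule list.

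Transcripts of macrophages and other leukocytes were among those that rose most. Of 15 tested markers 14 rose and none fell, with a median log2 fold change of 2.56 (camera, adjusted p = 3.46e-07, and adjusted p = 0.407 with an estimated correlation), and all 15 rose when adjusted over the list alone. Lyz2, which encodes lysozyme, rose from 2.93 ± 1.64 to 64.9 ± 39.4 FPKM, Laptm5 from 2.41 ± 1.5 to 33.3 ± 8.77, Fcgr3, an Fc receptor gene, from 1.49 ± 0.564 to 10.6 ± 4.19 and Aif1 from 1.44 ± 0.603 to 20.2 ± 14.0 FPKM (SD, n = 3 each; limma, adjusted p from 0.000267 to 0.00517). The complement gene C1qb rose from 10.1 ± 8.65 to 99.4 ± 67.9 FPKM (limma, adjusted p = 0.0144), a call lost without cKO 1 (adjusted p = 0.0553) or cKO 2 (0.0518). The median marker stood at 36.5, 47.0 and 8.51 FPKM in cKO 1, 2 and 3 and at 5.58, 3.34 and 2.12 FPKM in control 1, 2 and 3. Pf4 was the marker that did not pass over all genes. Without cKO 3 the list median moved to 3.43, with log2 fold changes of 4.58 for Lyz2, 3.55 for Aif1 and 3.98 for C1qb, which moved to 3.78 without control 1 and 2.49 without control 3.

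Genes that answer interferon were higher as well. Of 7 tested members 3 rose and none fell, 4 when adjusted over the list alone, with a median log2 fold change of 0.70 (camera, adjusted p = 0.00258, and adjusted p = 0.159 with an estimated correlation). The chemokine gene Cxcl10 rose from 1.24 ± 0.208 to 12.1 ± 8.09 FPKM, Ifi27 from 16.6 ± 3.78 to 50.4 ± 8.36 and Bst2 from 6.84 ± 1.60 to 24.2 ± 7.26 FPKM (SD, n = 3 each; limma, adjusted p from 0.000638 to 0.00195). The macrophage markers above were higher in the same libraries.

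Lists of the stroma, endothelium, ureteric epithelium and red blood cells did not pass over the 6 libraries, and single libraries stood apart in several of them. Of 19 stroma markers 3 rose, also over the list alone, namely Meis1 from 12.8 ± 1.89 to 25.1 ± 4.45 FPKM (SD, n = 3 each; limma, adjusted p = 0.00446), Acta2, smooth muscle actin, from 21.9 ± 8.45 to 46.4 ± 10.3 (0.0199) and Fibin from 2.74 ± 1.17 to 6.40 ± 1.58 (0.0252). Acta2 lost its call without cKO 1 (adjusted p = 0.0541) or cKO 2 (0.0695), and Fibin without control 1, control 3, cKO 1 or cKO 2 (0.0629 to 0.0885). The stroma list had a median log2 fold change of 0.18 (camera, adjusted p = 0.237), and its median marker stood at 9.64 FPKM in control 1 against 24.8 and 21.8 FPKM in control 2 and 3. The direction of the list turned down without control 1 (adjusted p = 0.837). In fits where control 1 was the lone control, it passed upward, without control 2, control 3 and cKO 3 (median 1.27, adjusted p = 1.16e-07) and with Y-linked transcripts as a covariate (median 1.16, 5.16e-05). Of 9 endothelial markers 3 fell and 1 rose, against 4 and 2 over the list alone (median -0.30, camera, adjusted p = 0.200). Ramp2 fell from 289 ± 10.7 to 143 ± 8.05 FPKM and Plvap rose from 11 ± 0.143 to 23.8 ± 7.01 FPKM (limma, adjusted p = 0.000162 and 0.00586). The median endothelial marker stood at 7.77, 8.02 and 6.99 FPKM in control 1, 2 and 3, far below Ramp2. Which of the sorted cells express Ramp2 was not tested. No member of the ureteric list of 11 genes passed, nor of the erythroid list of 8, also over the list alone (medians -0.41 and -0.51, camera, adjusted p = 0.204 and 0.140). Krt8, a keratin gene of the ureteric epithelium, stood at 26.4 ± 4.80 and 13 ± 11.2 FPKM (limma, adjusted p = 0.0690, and adjusted p = 0.000347 without cKO 3). The ureteric list passed without cKO 3 (adjusted p = 0.0157) and the erythroid list without cKO 2 (0.00536), both downward. The ureteric list also passed downward without a filter (0.0277) and, with control 1 as the lone control, without control 2, control 3 and cKO 3 (0.00725), and the endothelial list with the Y-linked covariate (0.0321).

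Transcripts of adrenal chromaffin cells appeared in 3 libraries of both groups. Th, tyrosine hydroxylase, stood at 57.6, 30.9 and 17.6 FPKM in control 2, control 3 and cKO 3 and below 1 FPKM in the others. Of 11 tested neural markers, which include Th and Dbh, 1 fell, also over the list alone. It was the neurofilament gene Nefl, from 3.96 ± 2.14 to 0.442 ± 0.645 FPKM (SD, n = 3 each; limma, adjusted p = 0.00915). The neural list had a median log2 fold change of -1.01 (camera, adjusted p = 0.188) and passed downward without control 1 (adjusted p = 0.00129). Its median was -0.011 without control 2, 0.022 without control 3 and -0.12 without cKO 3. Y-linked Ddx3y was found in control 2 (6.16 FPKM) and control 3 (8.55 FPKM) and was listed at 0 in control 1 and all 3 cKO libraries, so embryo sex was not balanced between the groups. Without the 3 libraries with chromaffin transcripts 1208 genes passed, and with the presence of Y-linked transcripts as a covariate 1151, both chosen after the data were seen. In both fits the control side of the comparison was control 1 alone (n = 1), which was assumed to vary like the other libraries.

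**Figure D3:**
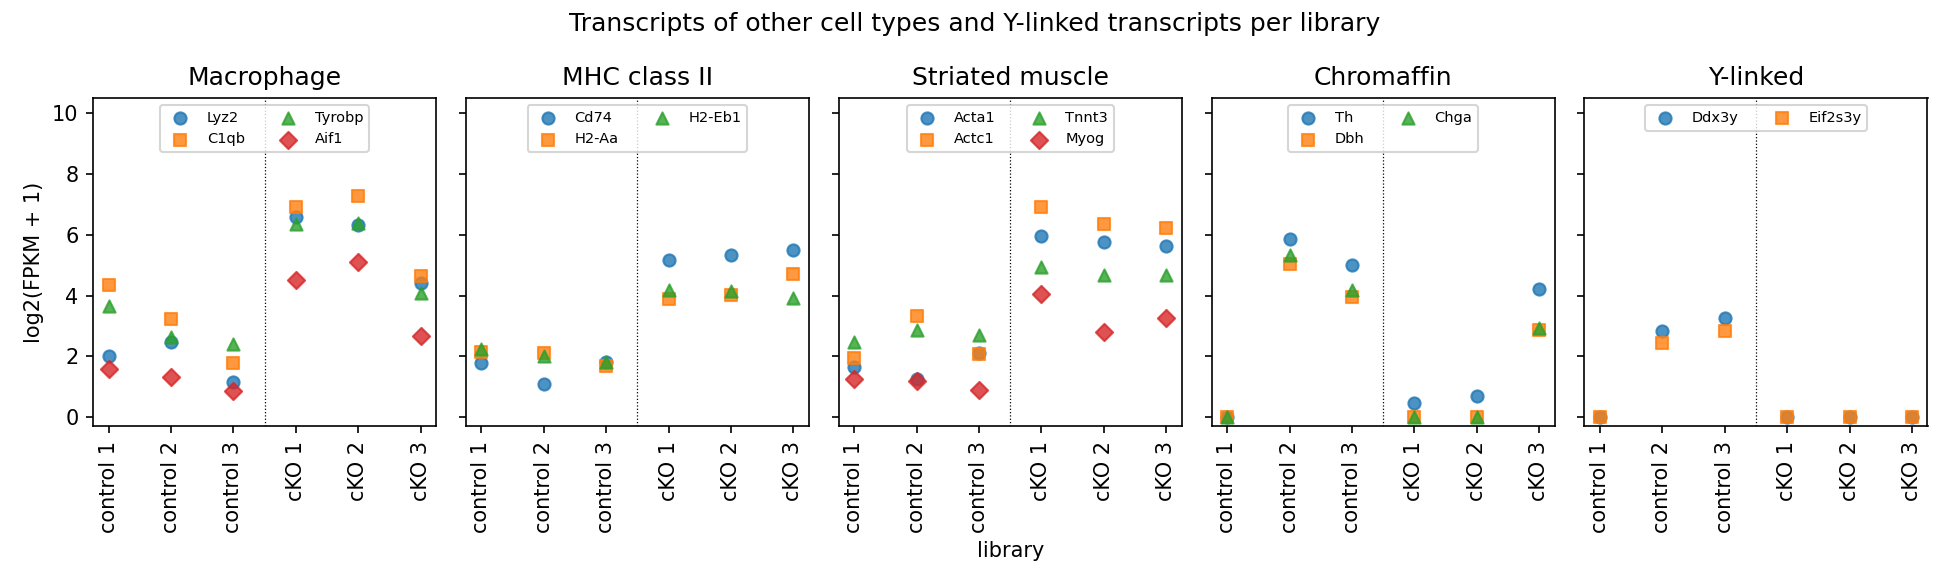
Log2(FPKM + 1) (vertical axis) of macrophage, MHC class II, striated muscle, adrenal chromaffin and Y-linked transcripts in each of the 6 libraries (horizontal axis, control left of the dotted line), with 1 point per gene. Th stood at 57.6, 30.9 and 17.6 FPKM in control 2, control 3 and cKO 3, and Ddx3y was found in control 2 and 3.

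Several genes of ribosome biogenesis and of glycolysis were lower in the cKO libraries. Of 30 listed genes of ribosome biogenesis 14 fell and none rose, 15 when adjusted over the list alone. The nucleolar genes Dkc1, from 113 ± 6.72 to 52.0 ± 3.52 FPKM, Gnl3, from 159 ± 2.60 to 81.0 ± 7.96, Npm1, from 898 ± 40.2 to 534 ± 21.5, and Nop58, from 145 ± 5.56 to 92.2 ± 6.06 FPKM, were among them (SD, n = 3 each; limma, adjusted p from 0.000182 to 0.00126). Ribosome biogenesis genes had a median log2 fold change of -0.35 (camera, adjusted p = 6.35e-05, and adjusted p = 0.221 with an estimated correlation). The deposited annotation's own pathway of ribosome biogenesis, examined after the data were seen, did not pass, with 11 of 70 genes lower and none higher (median -0.049, camera, adjusted p = 0.152). Of 20 glycolysis genes 8 fell and 1, Ldhb, rose, also over the list alone (median -0.24, camera, adjusted p = 0.000477, and adjusted p = 0.462 with an estimated correlation). Gapdh fell from 128 ± 6.09 to 72.2 ± 10.2 FPKM, Pkm from 438 ± 43.2 to 272 ± 20.2, Eno1 from 1876 ± 159 to 1226 ± 57.2 and the lactate transporter gene Slc16a1 from 43.9 ± 5.84 to 20.5 ± 3.54 FPKM (limma, adjusted p from 0.00144 to 0.00214). The list missed the threshold without the 3 libraries with chromaffin transcripts, where control 1 was the lone control (median -0.069, adjusted p = 0.0562). The wider glycolysis and gluconeogenesis pathway of the deposited annotation, examined after the data were seen, had 8 of 46 genes higher and 9 lower (median 0.0069, camera, adjusted p = 0.829).

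Of 87 genes named as ribosomal proteins 6 fell and 1 rose, against 4 and 1 over the list alone. Rpl3 fell from 669 ± 7.42 to 453 ± 7.58 FPKM, Rpl10 from 982 ± 18.8 to 668 ± 9.64, Rps4x from 536 ± 19.0 to 386 ± 11.8 and Rpl22l1, a paralog of Rpl22, from 261 ± 30.1 to 172 ± 7.45 FPKM (SD, n = 3 each; limma, adjusted p from 0.00115 to 0.00332). The gene that rose, Rps19bp1, encodes a binding partner of a ribosomal protein. The list had a median log2 fold change of -0.16 (camera, adjusted p = 0.000609, and adjusted p = 0.722 with an estimated correlation). Its call was lost without control 1 (adjusted p = 0.114) or cKO 3 (0.0998) and with fry (0.408). Its median was -0.057 without control 1, -0.066 without cKO 3 and -0.25 without cKO 1. The ribosome pathway of the deposited annotation, examined after the data were seen, did not pass, with 7 of 131 genes lower and 10 higher (median -0.082, camera, adjusted p = 0.489).

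Several feedback genes of receptor tyrosine kinase signalling were higher, and some Wnt targets were lower. Of 16 tested genes that respond to fibroblast growth factors through ERK 8 rose and 1 fell, against 9 and 1 over the list alone. Spry1, an inhibitor of the pathway, rose from 117 ± 33.0 to 282 ± 22.7 FPKM, Spry2 from 17.4 ± 3.42 to 41.4 ± 5.19 and Phlda1 from 37.5 ± 16.1 to 112 ± 8.12 FPKM (SD, n = 3 each; limma, adjusted p from 0.00117 to 0.00161). Ccnd1, which stands on 4 of the lists, was the member that fell. The median log2 fold change was 0.51 (camera, adjusted p = 0.0219, and adjusted p = 0.386 with an estimated correlation), and the adjusted p was 0.0526 without the 3 libraries with chromaffin transcripts, with control 1 as the lone control. Of 11 Wnt targets 4 fell, Ccnd1, Bmper, Znrf3 and Tnfrsf19, and 5 over the list alone (median -0.29, camera, adjusted p = 0.0425, and adjusted p = 0.496 with an estimated correlation). Bmper fell from 31.5 ± 4.17 to 14.1 ± 3.68 FPKM (limma, adjusted p = 0.00316). The Wnt median was -0.051 without control 1, -0.45 without control 3 and -0.71 without cKO 2. This list missed the threshold without control 1 (adjusted p = 0.252), cKO 1 (0.0678) or cKO 3 (0.167) and with the replicate number as a block (0.0572). It was also missed with quantile normalization (0.0623), upper-quartile scaling (0.0659), no filter (0.214), a minimum of 5 FPKM (0.0865), the length trend removed (0.0684) and fry (0.0854). Znrf3 lost its call without cKO 1 (adjusted p = 0.0553), and Tnfrsf19 without control 1, 2 or 3, cKO 1 or cKO 3 (0.0513 to 0.117). The Wnt signalling pathway of the deposited annotation, examined after the data were seen, did not pass, with 19 of 106 genes lower and 3 higher (median -0.06, camera, adjusted p = 0.151).

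Stress genes and Notch genes moved both ways. Atf3 rose from 28 ± 3.58 to 92.1 ± 12.2 FPKM and Ier3 from 15.7 ± 7.17 to 38.6 ± 8.48, whereas the heat shock genes Hspa1b fell from 22.6 ± 11.9 to 3.26 ± 2.82 and Hsp90aa1 from 559 ± 52.7 to 394 ± 28.5 FPKM (SD, n = 3 each; limma, adjusted p from 0.000133 to 0.00941). Hspa1b shares most of its sequence with Hspa1a, so its value is uncertain. Of 24 immediate early and heat shock genes induced by dissociation 5 rose and 2 fell, against 7 and 2 over the list alone, with a median of -0.04, a mean of 0.02 and a camera direction of up (adjusted p = 0.758) that turned without cKO 3 (0.242). Of 21 genes of the integrated stress and unfolded protein responses 5 rose and 4 fell, against 5 and 6 over the list alone, with a median of -0.02, a mean of 0.02 and a camera direction of down (adjusted p = 0.645). Creld2 rose from 78.4 ± 4.33 to 134 ± 10.7 FPKM and Phgdh, the entry enzyme of serine synthesis, fell from 481 ± 12.6 to 330 ± 23.2 FPKM (limma, adjusted p = 0.000938 and 0.00213). Of 9 Notch pathway genes Rfng and Mfng rose and Hey1 and Notch2 fell, also over the list alone (median -0.16, camera direction down, adjusted p = 0.645, turned without cKO 2 with 0.951), and with control 1 as the lone control, without the libraries with chromaffin transcripts, the list passed downward (0.0185). The Notch target Hey1 fell from 37.5 ± 13.2 to 13.7 ± 6.18 FPKM (limma, adjusted p = 0.00956), and Notch2 lost its call without control 2, control 3, cKO 1 or cKO 3 (adjusted p from 0.0533 to 0.0798).

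Among subunits of the histone H3 lysine 4 methyltransferase complexes, Ash2l and Psip1 fell and Cxxc1 rose. These were 3 of the 16 tested members, Ash2l included, also over the list alone, and the list did not pass (median -0.04, camera, adjusted p = 0.327, and 0.0331 downward with fry). Psip1 stood at 39.2 ± 3.93 and 28.4 ± 1.32 FPKM in control and cKO libraries and Cxxc1 at 31.0 ± 2.40 and 41.4 ± 1.78 FPKM (SD, n = 3 each; limma, adjusted p = 0.0180 and 0.0210). Psip1 lost its call without control 2 (adjusted p = 0.0763) or cKO 2 (0.0552), and Cxxc1 without control 1, control 2, cKO 1 or cKO 2 (0.0553 to 0.0810). Of 3 tested germline genes Rhox5, an X-linked homeobox gene, rose from 2.24 ± 0.551 to 15.2 ± 4.39 FPKM (limma, adjusted p = 0.000392). Rhox9 stood at 7.12 ± 4.16 and 2.18 ± 0.496 FPKM (adjusted p = 0.0651, and 0.00343 without control 3). Over the list alone 1 germline gene rose and 1 fell (median 0.21, camera direction up, adjusted p = 0.599, turned without control 3 with 0.675).

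Among the genes named by rule and on the log2(FPKM + 1) scale, the largest rises outside the leukocyte list were in the sarcomeric actin genes Acta1 and Actc1. A ratio of group means can order genes with low values otherwise. Acta1 rose from 2.27 ± 0.976 to 54.6 ± 6.63 FPKM and Actc1 from 5.03 ± 3.42 to 91.5 ± 25.0 FPKM, with log2 fold changes of 4.12 ± 0.22 and 4.05 ± 0.34 (SE, limma, adjusted p = 2.98e-05 and 0.000165). Cd74, the invariant chain of MHC class II, rose from 2.01 ± 0.776 to 39.9 ± 4.68 FPKM, the chemokine gene Ccl4 from 8.57 ± 6.51 to 111 ± 81.1, the cartilage matrix gene Matn1 from 1.09 ± 0.746 to 14.7 ± 0.407 and the lipid flippase gene Atp8a2 from 1.03 ± 0.438 to 14.3 ± 3.04 FPKM (SD, n = 3 each; limma, adjusted p from 4.16e-05 to 0.00881). The log2 fold change of Ccl4 moved from 3.32 to 4.20 without cKO 3. Among the largest falls were those of Cdo1, cysteine dioxygenase, from 59.0 ± 6.93 to 4.92 ± 0.686 FPKM, Afp, alpha-fetoprotein, from 10.6 ± 7.44 to 0.105 ± 0.181, Arhgdig from 16.3 ± 2.91 to 1.1 ± 0.952, the transcriptional cofactor gene Eya2 from 26.1 ± 6.92 to 2.71 ± 0.861, Hdc, histidine decarboxylase, from 6.09 ± 2.30 to 0.0144 ± 0.0250 and Cenpv from 21.7 ± 7.07 to 2.51 ± 1.48 FPKM (limma, adjusted p from 1.30e-05 to 0.00161).

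The authors' deposited table of this comparison gives q-values for 16709 genes, of which 3403 lie below 0.05, and marks 810 genes as up and 756 as down. Of the 2736 genes that passed here, 2531 (92.5%) also had a q-value below 0.05 in the authors' deposited table, all 2531 with the same direction. In the authors' deposited table the fold of Ash2l was 0.410 (q = 2.81e-15), that of Cdkn1c 4.0 (q = 7.03e-89) and that of Wnt4 0.247 (q = 2.05e-23).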

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

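Scaling by median ratio or upper quartile, limma-voom on recovered reads, the 1.5-fold threshold, robust empirical Bayes, the Y-linked covariate, the removal of 3 libraries and of a length trend were chosen after the data were seen. Of 138 named genes 118 passed, and none of these reversed under an alternative that tested it: 2217 of 2310 values kept the call and 93 lost it, and 89 genes kept it wherever tested. These genes were named in large part for large changes or small p-values in the same data, which favours kept calls. Across the alternative scalings, filters and left-out libraries, 100% of all genes that passed in the main fit kept their sign where tested. A gene that an alternative filtered out or removed has no value there. The count of genes was 1818 to 2524 without any 1 library (923 to 1308 higher, 784 to 1216 lower), 2769 with limma-voom and 2297 without a filter. It was 1354 at adjusted p 0.01 (706 higher, 648 lower), 784 with a 2-fold minimum (404 and 380) and 309 against a 1.5-fold threshold (153 and 156), by construction fewer. It was 1208 without the chromaffin libraries (700 and 508) and 1151 with the Y-linked covariate (642 and 509). By construction control 1 is then the lone control (n = 1), assumed to vary like the other libraries, so values from these fits rest on that library.

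Without each library in turn, Ash2l had a log2 fold change of -1.38 to -1.10. List adjusted p-values then ranged from 1.57e-23 to 8.99e-20 (replication), 1.4e-31 to 2.92e-28 (mitosis), 0.563 to 0.948 (G1 control), 0.000329 to 0.00214 (progenitor), 5.4e-05 to 0.00298 (early nephron), 0.0262 to 0.162 (podocyte), 5.25e-07 to 0.0566 (proximal tubule) and 0.0665 to 0.447 (loop and distal). With an estimated correlation they were 0.0942 (replication), 0.144 (mitosis), 0.261 (progenitor and early nephron), 0.386 (podocyte) and 0.259 (proximal tubule). With fry, which does not compare a list with other genes, they were 0.000681 (replication), 0.00205 (mitosis) and 0.00808 (progenitor). Fry also gave 0.0199 (early nephron), 0.0135 (podocyte) and 0.00574 (proximal tubule), and these lists all went downward. The podocyte list had 0.247 at a minimum of 5 FPKM. The loop and distal list passed without a filter (0.024), with the Y-linked covariate (0.0254) and with fry (0.0253). Fry turned G1 control (0.42) and the stress response list (1) upward.

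Reversals met results that had not passed. With the Y-linked covariate log2 fold changes turned for Ahsp (0.32), Dbh (0.95), Snap25 (0.55) and Rhox6 (-0.14), and the neural (adjusted p = 0.203) and early response lists (0.831) turned. Without the chromaffin libraries Ahsp (0.45) and the early response list (0.0906) turned. Leaving out single libraries turned Six2 (log2 fold changes of -0.14 to 0.036), Rhox6 (-0.39 to 0.64) and the stroma (adjusted p 0.0502 to 0.837), germline (0.381 to 0.675), Notch (0.358 to 0.973) and early response lists (0.242 to 0.982). The cause was not tested.

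Same-numbered libraries of the groups correlated in their deviations at 0.19, 0.01 and 0.20, so the numbers were not taken as pairs. The sample descriptions number the control libraries otherwise than the titles do, so the block rests on the replicate numbers of the titles alone. With the replicate number as a block 3030 genes passed, and not every library correlated best with its own number. Tests that need deposited counts (DESeq2, edgeR, TMM or RLE factors, glmTreat) were not run. Depth differed little between libraries. At 3 against 3, fewer than 50% of 1.5-fold changes were found in the simulation, which used a single dispersion for all genes.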

Other observations

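The gene groups of the next 2 paragraphs, the muscle and MHC class II genes and all tests of explanations below were chosen after the results were seen. Among 307 pathways of the deposited annotation with at least 10 tested genes, 35 passed (camera, adjusted p below 0.05), 22 of them upward, and none with an estimated correlation. Oxidative phosphorylation rose, with 31 of 108 genes higher and 3 lower (adjusted p = 1.53e-05, and adjusted p = 0.989 with an estimated correlation). The complex III genes Cyc1 rose from 363 ± 2.35 to 553 ± 35.2 FPKM and Uqcrc1 from 505 ± 27.8 to 740 ± 31.3 FPKM, and the complex I gene Ndufv1 from 201 ± 11.6 to 295 ± 19.9 FPKM (SD, n = 3 each; limma, adjusted p from 0.00122 to 0.00263). Lysosome genes rose, 27 of 109 against 4 that fell (adjusted p = 0.0147, and adjusted p = 0.989 with an estimated correlation), in the libraries with higher macrophage markers. The lysosomal protease gene Ctsd rose from 171 ± 12.5 to 326 ± 52.7 FPKM and Ctsl fell from 99.7 ± 5.57 to 46.6 ± 6.96 FPKM. Spliceosome genes fell, 24 of 127 against 6 that rose (adjusted p = 0.00369, and adjusted p = 0.66 with an estimated correlation), among them Magohb, of the exon junction complex, from 42.5 ± 5.24 to 9.19 ± 1.69 FPKM and Hnrnpa1 from 551 ± 46.8 to 305 ± 13.4 FPKM. All 3 pathways passed in the same direction under quantile, median-ratio and upper-quartile scaling, with the length trend removed and without each library in turn. Fold changes were related to gene length, with a median of 0.11 (log2) over the 2151 genes of up to 1699 bases and of -0.06 over the 2150 genes of at least 5590 bases.

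Hox genes, which set position along the body axis, changed in both directions. Of 30 tested, 8 rose and 11 fell. Hoxb1, a gene of the anterior end of its cluster, stood at 0.122 ± 0.139 FPKM in control and 6.89 ± 1.17 FPKM in cKO libraries (SD, n = 3 each), a log2 fold change of 2.81 ± 0.20 (SE, limma, adjusted p = 0.000101). Hoxb5 rose from 22.8 ± 3.84 to 57.4 ± 5.46 FPKM and Hoxb6 from 30.8 ± 2.81 to 61.2 ± 3.67 FPKM. Hoxa9 fell from 57.9 ± 5.86 to 12.5 ± 1.62 FPKM, with a log2 fold change of -2.13 ± 0.13 (limma, adjusted p = 6.87e-05), and Hoxc10 fell from 43.3 ± 3.79 to 15.9 ± 2.84 FPKM. All 19 kept their sign under quantile, median-ratio and upper-quartile scaling, as did 100% of all genes that passed. The counts that rose and fell were 8 and 10 with median-ratio scaling and 8 and 12 with upper-quartile scaling. They were 7 and 9 without control 1 and 6 and 12 without cKO 1. Hoxb1 fell below the filter and was not tested when a cKO library was left out.

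The count of 2736 genes is the highest of the 10 splits of the 6 libraries into 3 and 3, and the highest of the others gave 0 (limma, adjusted p below 0.05). As 1 of 10 is the smallest share this design allows, the splits are too few for a share under 0.05. Each of the other splits mixes both genotypes, so the genotype difference enlarges the spread within its groups. Their count of 0 is therefore no measure of what arises without a genotype difference.

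Macrophage markers were higher in the cKO libraries, although the cells were sorted for GFP. Transcripts of other cell types were present in sorted libraries of both groups. The median macrophage marker stood at 5.58 FPKM in control 1, and Th at 57.6 FPKM in control 2 and 17.6 FPKM in cKO 3. A lower share of the sorted lineage would raise every other cell type alike if all were carried over equally. That equal rise was not seen, as the macrophage median lies 2.37 (log2) above the highest of the ureteric, stroma, endothelial, erythroid and neural medians. The SD of 0.427 is the spread of those medians, not an error of the difference. A lower share with unequal carry-over is not excluded. The median stroma marker, for example, stood at 9.64 FPKM in control 1 against 24.8 and 21.8 FPKM in control 2 and 3. More macrophages among the sorted cKO cells may be a source, since all 15 of 15 tested markers, Lyz2 and C1qb with them, were lower in cKO 3 than in cKO 1 and cKO 2. Genes that change together within the sorted cells would give the same result, and whether a larger number of macrophages follows the genotype or the dissociation stays open. MHC class II genes did not follow the macrophage list within the cKO group, with a median log2 ratio of cKO 3 over cKO 1 and 2 of 0.43 over 4 genes (-0.26 to 0.80) against -2.33 over the 15 markers; H2-Ab1 did not pass over all genes (limma, adjusted p = 0.192).

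A set of 8 striated muscle genes was chosen because its members rose, from Acta1 and Actc1 to the troponin genes Tnnt3 (5.45 ± 0.89 to 26.5 ± 2.98 FPKM) and Tnnc2 and the myogenic regulator Myog (1.2 ± 0.28 to 10.1 ± 5.07 FPKM; SD, n = 3 each). A source in skeletal muscle cells stays open. The median of 26 genes of skeletal muscle, the 8 included, in cKO libraries was 0.307 FPKM. This is 2.88% of the median of the 8 rising genes (10.7 FPKM), a comparison that cannot decide because the 8 were picked for their rise. Ckm, Myh3 and Ttn stayed below 1 FPKM in cKO libraries, which argues against cells that express them strongly. Tnni2, however, rose from 6.79 ± 3.0 to 33.0 ± 2.04 FPKM and Myom1 from 0.15 ± 0.13 to 1.60 ± 0.48 FPKM (SD, n = 3 each, limma, adjusted p = 0.000472 and 0.00431). For heart muscle cells the same comparison (16 genes of heart muscle, 0.194 FPKM, 1.82%) cannot decide for the same reason. Myh6 and Myh7 stayed below 1 FPKM in cKO libraries, which argues against cells that express them strongly. Myl7, however, rose from 0.717 ± 0.545 to 5.32 ± 0.628 FPKM (SD, n = 3 each, limma, adjusted p = 0.00103). Tnni3 rose from 1.48 ± 0.697 to 4.21 ± 1.34 FPKM (limma, adjusted p = 0.01999). A source in heart muscle cells stays open. More stromal or smooth muscle cells stay open as well. The muscle median lies 1.99 (log2) above that of the stroma list, but the muscle genes were picked for their rise and Acta2 of that list rose as well. Muscle precursors that do not yet express Ckm or Myh3 were not tested, and a candidate explanation, as a hypothesis left untested, is that cells of the sorted lineage switch on part of the muscle programme after the loss of Ash2l.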
